A study of Mus musculus with 2 samples.

How the data were processed

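Live cells carrying CD45 were sorted by flow cytometry from MC38 tumours after enzymatic digestion, per the labels' protocols, and cells of 5 biological replicates were pooled into each of 2 libraries, one of a control group (Ctrl) and one of a treated group (BiDT). Per the labels, both libraries belong to batch 1. The labels give no definition of the name BiDT, and the series title names a fusion of an anti-TIM3 antibody with an interferon. The deposited values are raw UMI counts per gene and cell barcode, with no normalization, for 32589 genes with Ensembl identifiers and symbols. Per the submitters' processing notes, Cell Ranger 7.1.0 and the GRCm39 genome build were used, and per the labels' protocols the libraries followed a 10x Genomics 3' workflow. The barcodes in the deposited count files have 3 segments of 9 bases joined by low lines, which is not the form that Cell Ranger writes. Neither the library workflow nor the counting step is therefore certain. The annotation release is not given in the sources used here. No coordinates are given, since the reference at hand was of another build, and genes are named as in the files. A total of 48 symbols were borne by more than 1 gene, and 8 symbols of the gene lists were absent from the files.

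Cells with at least 300 genes and 500 UMIs and at most 10% mitochondrial UMIs were kept. Doublets were scored in each library with Scrublet (scanpy 1.11.5, expected rate 5%). Its own thresholds of 0.574 and 0.577 marked 0 cells and had thus not worked, and cells scoring 0.15 or more were removed instead, 2168 in Ctrl (6.65%) and 2732 in BiDT (7.94%). That value was chosen after the scores had been seen. The mitochondrial filter removed 1702 Ctrl and 572 BiDT cells, and 30439 and 31691 cells remained. With a floor of 3 cells, rather than the exact interval, a count of 0 cells allows a share of up to 0.0099% and 0.0095%.

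Cells of both libraries were clustered together with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and igraph 0.11.9 (logarithm of counts per 10000, 3000 variable genes chosen within each library, 30 principal components, 15 neighbours, Leiden resolution 1). T and NK cells, and dendritic cells together with the rarer B, plasma and mast cells, were each clustered again. Genes of both interferon lists, mitochondrial and ribosomal genes and receptor segments were left out of the clustering, but other interferon-induced genes were not. Clusters were named from markers fixed before the data were examined. A cluster stayed unnamed with fewer than 3 markers detected in 10% of its cells, with a marker score of another lineage at 0.75 or more of its own, with more markers of other classes than of its own among its 10 leading genes, or, for CD8 T-like cells, with Cd8a or Cd8b1 detected in less than 50% of the share of the highest cluster. The last criterion, the score ratio, the doublet threshold and the counting of leading markers by class were settled after first cluster shares had been seen. Clusters that these rules kept unnamed were L11 (0.749% of Ctrl and 1.28% of BiDT cells) and L15 (0.030% and 0.464%), with low Cd8a or Cd8b1, L9 (0.437% and 1.80%), L14 (0.194% and 0.439%), L12 (0.716% and 0.817%) and D9 (0.171% and 0.098%), whose leading genes held more markers of other classes than of the class that scored highest, and 21 (0.315% and 0.104%), where another lineage scored at 0.75 or more of the highest. The leading genes were granzyme genes such as Gzmd in L9 and Gzmg in L14, Ccl1, Il13 and Cd4 in L12, Ccr7 and Ccl22 in D9, and Ctsk and Mmp9 in 21. Klra7 and Tcf7 were among the leading genes of L11, and histone genes such as H4c6 led L15. Without the CD8 criterion the log2 ratio of the CD8 T-like share was 0.82 instead of 0.78.

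Shares have exact (Clopper-Pearson) 95% binomial intervals. For expression, UMI counts were summed per class and library, given as CPM, counts scaled to a common total of the class, and compared as log2 of BiDT over Ctrl with an exact conditional binomial 95% interval. A list was described by the median log2 ratio of members with at least 50 UMIs over both libraries, with an interval from 2000 Poisson draws, its percentile among 10000 random lists matched on expression, and the members at least 1.5 times higher or lower. Members with a CPM below 10% of that in another named class in both libraries were marked as within reach of free RNA. Unnamed clusters were not part of that comparison. For Havcr2 detection each cell was thinned to 1000 UMIs, which left out no filtered cell. With 1 library per group there was no test between groups.

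The named genes followed a rule fixed before the data were examined. In CD8 T-like, DC-like, macrophage or monocyte-like and all filtered cells they are the 10 highest and 10 lowest log2 ratios among genes with at least 50 UMIs and 50 CPM whose interval excludes 1-fold. Mitochondrial, ribosomal, receptor, predicted, sex-linked and free-RNA-range genes were left out. Members of 16 fixed lists at least 1.5 times higher or lower could be named as examples, as could a set of fixed genes that includes Havcr2, Gzmb, Ifng and Mki67. The lists cover type I interferon and interferon gamma responses, MHC class I and class II presentation, DC activation, cytotoxicity, exhaustion, progenitor and memory cells, regulatory T cells, proliferation, macrophage suppressive and inflammatory genes, chemokines, glycolysis, early response genes, and TIM3 with interferon receptors. A sterol synthesis list of 20 genes was drawn up after several of its genes had been seen among the lowest ratios, and Malat1, the genes of the with-and-without Havcr2 comparison outside the fixed set, and those used to describe fibroblast-like cells were chosen after the data had been seen.

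The ratio and list steps were tested on simulated counts for CD8 T-like cells over 10820 genes, of which 200 were changed. Both libraries were drawn as Poisson counts from their pooled profile, the model that the interval assumes. The simulation thus checks the computation alone and holds no spread between cells or animals. The interval excluded 1-fold for 4.6% of unchanged genes, 96.0% of genes changed 2-fold and 99.0% of those changed 4-fold, and a list of 50 genes changed 4-fold had a median log2 of 1.99. Alternatives planned before the data were examined were at least 500 genes, at most 5% mitochondrial UMIs, doublets kept, Leiden resolutions of 0.5 and 2, interferon lists kept in the clustering, thinning, TMM factors (edgeR 4.0.16 in R 4.3.3), median-of-ratios size factors, means over cells, no UMI minimum, no thinning for Havcr2 and at least 2 Havcr2 UMIs. Doublet thresholds of 0.1 and 0.2, cells above the lowest Ctrl total, cells with Malat1 at 1% of UMIs or less, and no CD8 criterion were added after seeing the data. Figures were drawn with matplotlib 3.10.9.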

Results

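Tumours of MC38, a mouse colon carcinoma line, were collected 19 days after inoculation, and live cells carrying CD45, the surface marker of leukocytes, were sorted from them for single-cell RNA sequencing. Per the labels' protocols, cells of 5 biological replicates per group were pooled before library construction, so that 1 library represents the control group (Ctrl) and 1 library the treated group (BiDT). The series title names a fusion of an anti-TIM3 antibody with an interferon, exhausted CD8 T cells that carry TIM3, and dendritic cells of the tumour, and the comparison therefore asks how these cells and their neighbours differed after treatment. Because each group is 1 library, no difference below has a test or a replicate check, and every interval covers counting error only. The Ctrl library held 34310 barcodes with 211047063 UMIs, a median of 4126 UMIs and 1719 genes per barcode, and the BiDT library 34996 barcodes with 130313537 UMIs, a median of 2652 UMIs and 1299 genes. Filters left 30439 Ctrl and 31691 BiDT cells, at median depths of 4173 and 2618 UMIs. In filtered cells Malat1, a noncoding RNA retained in the nucleus, took 0.41% of UMIs in Ctrl and 0.82% in BiDT. The median mitochondrial share of filtered cells was 1.69% and 1.0%. Scaling by trimmed mean of M-values (TMM) instead of by total counts shifts every log2 ratio below by -0.06 in CD8 T-like, -0.15 in DC-like and -0.19 in macrophage or monocyte-like cells and by -0.22 over all cells.

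The leukocytes of the BiDT library held proportionally more NK and CD8 T cells and fewer macrophages and dendritic cells. NK-like cells made up 3.72% of filtered Ctrl cells (exact 95% interval 3.51 to 3.93%) and 16.1% of BiDT cells (15.7 to 16.5%), a 4.33-fold higher share. CD8 T-like cells took 6.52% (6.24 to 6.80%) and 11.2% (10.8 to 11.5%), and neutrophil-like cells 2.45% and 5.29%. Macrophage or monocyte-like cells, the most numerous class in both libraries, stood at 69.2% (68.7 to 69.7%) in Ctrl and 52.9% (52.4 to 53.5%) in BiDT. Dendritic cell-like (DC-like) cells were 2.71-fold less frequent in BiDT, at 7.97% (7.67 to 8.28%) and 2.94% (2.76 to 3.13%). Plasmacytoid DC-like cells stood at 0.204% and 0.063%, and plasma cell-like cells at 0.039% and 0.110%. B-like cells numbered 7 in Ctrl and 21 in BiDT, and mast cell-like cells 10 and 12. A fibroblast-like class held 5.38% and 5.20%, a log2 ratio of -0.05 that ranged from -1.38 to 0.06 over 11 alternatives. It was unanticipated in a CD45 sort and named by markers that do not tell fibroblasts from MC38 tumour cells. All shares here are of sorted CD45-positive cells, so that a difference in 1 class shifts all others, and the depths of the libraries and their cell calling could set part of them. Clusters that met no naming rule held 2.61% of Ctrl and 5.005% of BiDT cells.

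**Figure D1:**
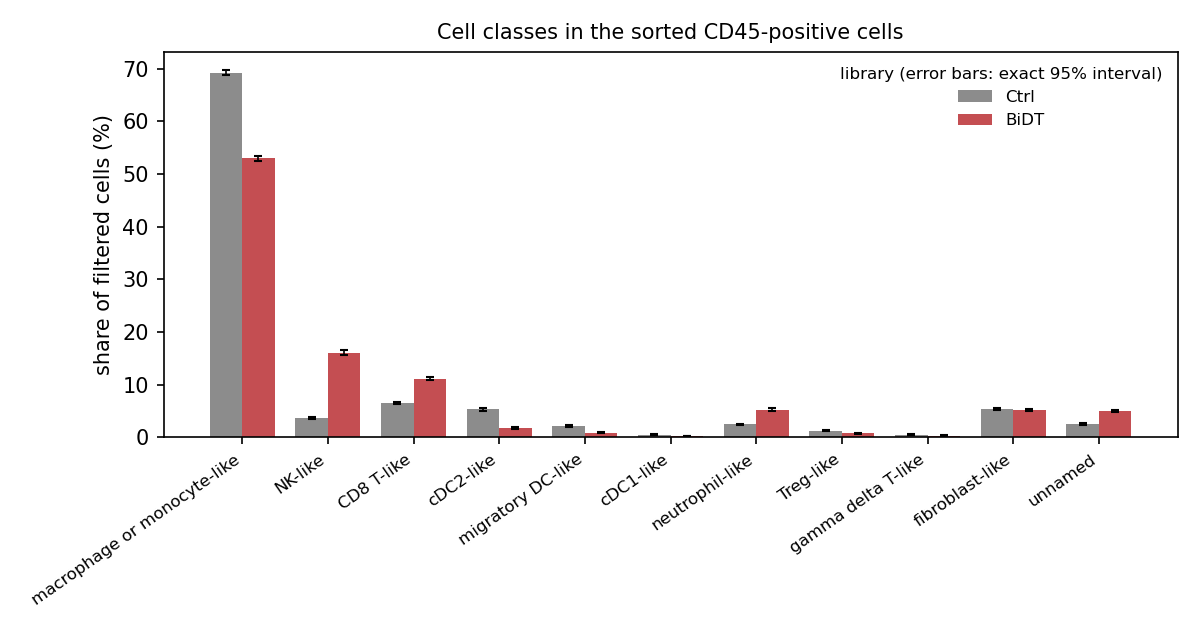
Share of filtered cells (%, vertical axis) in each named class with at least 50 cells in each library and in the unnamed clusters, for the Ctrl (grey) and BiDT (red) libraries, with exact 95% binomial intervals as error bars. NK-like cells stood at 3.72% in Ctrl and 16.1% in BiDT, and macrophage or monocyte-like cells at 69.2% and 52.9%.

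Within the lymphoid compartment the balance of subsets also differed, while that of the dendritic subsets differed less. T and NK clusters together took 14.2% of Ctrl and 33.2% of BiDT cells. Of these, NK-like cells made up 26.2% in Ctrl (24.9 to 27.5%) and 48.6% in BiDT (47.6 to 49.5%), and CD8 T-like cells 45.9% (44.5 to 47.4%) and 33.7% (32.8 to 34.6%). Regulatory T-like cells, marked by the transcription factor Foxp3, were 9.06% of the T and NK clusters in Ctrl (8.22 to 9.95%) and 2.38% in BiDT (2.10 to 2.69%), and gamma delta T-like cells 3.82% and 0.895%. As shares of all filtered cells, regulatory T-like cells stood at 1.29% and 0.789%. Among DC-like cells, type 2 conventional DC-like (cDC2-like) cells made up 67.0% in Ctrl (65.1 to 68.9%) and 60.8% in BiDT (57.6 to 64.0%). Migratory DC-like cells, marked by the chemokine receptor Ccr7, took 26.8% (25.05 to 28.6%) and 30.8% (27.8 to 33.9%), whose log2 ratio of 0.20 had an interval that includes 0. Over 6 alternatives that ratio ranged from 0.24 to 0.47, all above the reported value. The log2 ratio of the cDC2-like share was -0.14, and -0.21 to -0.16 over 6 alternatives. Type 1 conventional DC-like (cDC1-like) cells took 6.19% and 8.37%, a log2 ratio of 0.44 that became -0.03 when clustering at a Leiden resolution of 2. As shares of all filtered cells, each of these DC subsets was lower in BiDT, from 5.34% to 1.79% for cDC2-like, 2.14% to 0.906% for migratory DC-like and 0.493% to 0.246% for cDC1-like cells. All of these subsets come from a sort on CD45 alone.

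CD8 T-like cells of the BiDT library carried a strong type I interferon response together with more Gzmb and Ifng transcripts, while most exhaustion genes differed little. All 46 measured members of the type I interferon list were at least 1.5 times higher in BiDT, with a median log2 ratio of 3.13 (95% counting interval 2.96 to 3.36), and 4 of the 46 lay below 10% of another class's CPM. Gzmb, which encodes the cytotoxic protease granzyme B, stood at 1331 CPM (UMIs of the gene scaled to a common total of the class) in Ctrl and 4478 CPM in BiDT, a log2 ratio of 1.75. Ifng, the gene of interferon gamma, stood at 449 and 753 CPM (log2 0.75). The 10 highest ratios among genes that passed the filters all belonged to the type I interferon list. Usp18, a deubiquitinase-like protease that restrains interferon receptor signalling, led with 5.22 CPM in Ctrl and 234 CPM in BiDT (log2 5.48, 5.04 to 5.97). It was followed by Cmpk2 (5.06), Ifit3 (4.84), Rtp4 (4.61), Ifit1 (4.52), Ifit1bl1 (4.42), Oas3 (4.36), Oas1a (4.32), the ubiquitin-like modifier Isg15 (4.30) and the transcription factor Irf7 (4.19).

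Other groups of genes in CD8 T-like cells differed less. Of the interferon gamma list, 17 of 24 measured members were at least 1.5 times higher and 2 lower (median 0.89), with 10 of the 24 below 10% of another class, Cxcl10 and Iigp1 among them. Members above that level included the immunity-related GTPase Irgm1 (2.20), the guanylate-binding protein Gbp4 (1.02) and the signalling inhibitor Socs1 (0.94). The MHC class I presentation list had 14 of 23 members higher and none lower (median 0.61), including H2-T22 (1.45), the peptide transporter Tap1 (1.03) and H2-K1 (0.78). The cytotoxicity and effector list had 7 of 28 members higher and 3 lower (median 0.07), with the chemokine Ccl4 at 0.88 and the cytokine gene Tnf at 0.90 on the higher side. The 10 lowest ratios held Ccl1, a chemokine (257 and 51.0 CPM, log2 -2.33), Xcl1, a chemokine that attracts cDC1 cells (-1.27), Emb (-1.19), Nrgn (-1.14), the chemokine receptor Cx3cr1 (-1.10), the chemokine Ccl5 (1264 and 599 CPM, -1.08), S100a11 (-1.03), Nrp1 (-1.02), Serpinb6b (-0.97) and Nmrk1 (-0.94). Ccl1 was also a leading gene of unnamed cluster L12, which the free RNA comparison left out. Ly6c2, a surface antigen of monocytes and of activated or memory CD8 T cells, stood at 360 and 2714 CPM (2.91). In the terminal exhaustion list, 3 of 20 members were at least 1.5 times higher and none lower (median -0.11), and among the higher were the ectonucleotidase Entpd1 (0.72) and the transcription factor Prdm1 (0.59). Pdcd1, which encodes PD-1, had a log2 ratio of -0.21, the exhaustion regulator Tox -0.39 and Havcr2, which encodes TIM3 (ENSMUSG00000020399), 0.40. The progenitor and memory list had 3 of 21 members higher and 4 lower (median -0.40, between -0.46 and -0.06 over 16 alternatives), with the transcription factors Bach2 at -0.79, Klf2 at 1.03 and Myb at 0.81. Tcf7, the defining factor of progenitor exhausted cells, had only 44 and 54 UMIs and lay below 10% of another class's CPM. It was a leading gene of unnamed cluster L11, which scored highest for CD8 T cells. The Cd8a and Cd8b1 criterion kept L11 out of the CD8 T-like class, so the Tcf7 counts and the progenitor median describe the class without it.

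Proliferation genes were mostly slightly higher in these cells, with 5 of 26 at least 1.5 times higher and none lower (median 0.41), among them Ube2c (1.19), Cenpf (1.06) and Birc5 (0.73), and Mki67 at 0.41. The glycolysis and hypoxia list had a median of -0.24, with the glycolytic enzyme Gapdh at -0.93 as its 1 member at least 1.5 times lower of 23. The early response and heat shock list, which can mark tissue dissociation, had a median of 0.26, with Jun at 0.71 and Hsp90aa1 at 0.82 as the 2 higher of 22 members. The regulatory T cell program had a median of -0.12. The TIM3 and interferon receptor list had a median of 0.12 that turned to -0.02 in thinned counts, with the TIM3 ligand gene Lgals9 at 0.95 and the interferon receptor genes Ifnar1 and Ifnar2 at -0.34 and 0.09. Malat1 was higher as well (log2 0.82). All 12 measured MHC class II members lay below 10% of another class's CPM in both libraries, a range that free RNA can reach, and had a median of -0.76. The libraries filled the class with different clusters: cluster L4 held 57.2% of it in Ctrl and 5.40% in BiDT, and cluster L5 0.60% and 32.0%.

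DC-like cells of the BiDT library also had higher interferon genes, together with higher Cd86, Cd40 and Cd274 and lower sterol synthesis genes. Of the type I interferon list, 43 of 46 members were at least 1.5 times higher (median log2 1.68, 1.58 to 1.75). Cd86 and Cd40, costimulatory genes of antigen-presenting cells, stood at 382 and 682 CPM (0.84) and at 119 and 187 CPM (0.65), and Cd274, which encodes PD-L1, at 238 and 393 CPM (0.72). The chemokine Cxcl10 was higher at 355 and 1195 CPM (1.75), whereas Cxcl9, another ligand of the receptor CXCR3, was lower at 621 and 429 CPM (-0.53). In the DC activation list, 11 of 26 members were at least 1.5 times higher and 1 lower, with a median of 0.37 that was 0.13 in cells with Malat1 at 1% or less, a setting chosen after seeing the data, and 0.23 with TMM scaling. By subset the median was 0.42 in cDC2-like, 0.20 in migratory DC-like and -0.97 in cDC1-like cells, with ranges over 15 alternatives of 0.11 to 0.55, 0.03 to 0.42 and -1.24 to -0.08. Higher members included Il15 (1.44) and its receptor chain Il15ra (0.85), which present interleukin 15 to T and NK cells, and Tnfsf4 (1.12), and the lower one was the chemokine Ccl17 (-0.67). The costimulatory genes Cd80 (0.43) and Cd83 (0.30) stayed below that size. Il12b, a subunit of interleukin 12, was at 131 and 147 CPM (0.16), and Ccr7 at 1201 and 1101 CPM (-0.13).

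Of the 10 highest ratios in DC-like cells, 9 were type I interferon genes: Ifit3b (4.52), Rsad2 (3.97), Ifit2 (3.64), Ifit1 (3.63), Ifit3 (3.45), Cmpk2 (3.10), Oasl1 (2.95), Ifi44 (2.72) and Slfn8 (2.59), and the other was the phosphodiesterase Pde7b (2.84). The interferon gamma list had 15 of 24 members higher and none lower (median 0.86), with the transcription factor Irf1 at 1.08 and the GTPase Iigp1 at 1.14. MHC class I genes had a median of 0.26 (0.11 with TMM scaling) with 5 of 23 higher, among them H2-T22 (1.12) and H2-Q4 (1.11), and MHC class II genes one of -0.35 (-0.18 in cells with Malat1 at 1% or less) with 4 of 14 lower, among them H2-Oa (-0.81) and H2-DMb2 (-0.70), and 1 higher, the endopeptidase Lgmn (0.77). The chemokine list had 10 of 19 members higher and 2 lower (median 0.76, thinned 0.31), with Ccl4 at 1.85 and Pf4 at 1.80, but 8 of the 19 lay below 10% of another class. Sterol synthesis genes, a list drawn up after their values had been seen, were lower in 16 of 20 members (median -1.03), as in Hsd17b7 (-2.24) and Dhcr7 (-2.03). The 10 lowest ratios were Asgr2 (-1.95), the sterol genes Fdps (-1.76), Sqle (-1.54) and Msmo1 (-1.13), the desaturase gene Scd2 (-1.49), fibronectin, Fn1 (-1.50), the complement genes C1qc (-1.29) and C1qb (-1.19), Ifitm1 (-1.24) and Qpct (-1.12). In Ctrl, Fn1 stood at 215 CPM here and 2495 CPM in macrophage or monocyte-like cells, thus below 10% and within reach of free RNA. In BiDT, at 76.1 and 566 CPM, it lay above 10%, so the rule for both libraries kept it. C1qb and C1qc are macrophage markers, whereas other genes of monocytes or macrophages were higher, such as Ly6c2 (1.88), Fcgr1 (0.65) and, below 10% of another class, Retnla (2.21) and Ccl7 (2.35). The macrophage inflammatory list had 10 of 22 members higher and 1 lower (median 0.34), with 6 of the 22 below 10% of another class, and the tissue-resident and suppressive list 2 of 19 higher and 6 lower (median -0.06). Malat1 was higher in DC-like cells (1.41). Genes of T and NK cells were higher too, with 19 of 23 members of the cytotoxicity list at least 1.5 times higher (median 1.81), 14 of the 23 lying below 10% of another class, and Gzmb at 8.13 and 96.7 CPM (3.57). Havcr2 stood at 124 and 128 CPM (0.05). The libraries drew on different clusters here too, with cluster D0 holding 22.8% of the cDC2-like cells in Ctrl and 45.3% in BiDT and cluster D6 20.6% and 50.9% of the migratory DC-like cells. D0 and D6 had medians of 2087.5 and 2104.5 UMIs per cell, the lowest among the clusters of their classes. D0 had 0 cDC2 markers among its 10 leading genes. Whether these clusters set part of the DC-like ratios was not tested.

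Macrophage or monocyte-like cells of the BiDT library combined a type I interferon response with lower MHC class II, proliferation and sterol synthesis genes. All 46 members of the type I interferon list were at least 1.5 times higher (median log2 2.44, 2.42 to 2.46). Of the MHC class II list, which presents antigen to CD4 T cells, 12 of 14 members were lower and 1 higher (median -0.95), with 4 of the 14 below 10% of another class. H2-Eb1 stood at 2955 and 1105 CPM (-1.42), H2-Aa at -1.09, the invariant chain Cd74 at -0.91 and Lgmn at 1.14. Of the proliferation list, 24 of 26 members were at least 1.5 times lower and none higher (median -1.51), as in Ccnb1 (-2.37), Ccna2 (-2.27), Top2a (-1.84) and Mki67 (156 and 40.7 CPM, -1.94). Sterol synthesis genes were lower in 19 of 20 members (median -1.61), as in Fdps (101 and 13.2 CPM, -2.93) and the epoxidase Sqle (-2.66).

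The highest ratios in macrophage or monocyte-like cells held 9 interferon list genes, Ifit3b (5.55), Ifit1bl1 (4.96), Ifi44 (4.95), Ifit3 (4.55), Ifi208 (4.13), Ifit2 (4.10), Ifit1 (4.04), Cmpk2 (3.89) and Rsad2 (3.89), and the schlafen gene Slfn4, at 56.3 and 1678 CPM (4.90). Besides sterol and proliferation genes (Fdps, Idi1 at -2.12, Cyp51 at -2.005, Pclaf at -2.17, Birc5 at -1.96 and Mki67), the 10 lowest were the glycolytic gene Aldoc (-2.16), Fn1 (2495 and 566 CPM, -2.14), Scd2 (-2.09) and the lectin Mgl2 (-2.03). The interferon gamma list had 19 of 25 members higher and 2 lower (median 1.38), with Tgtp1 at 2.28 and Irgm1 at 1.83. Its member Cxcl10 stood at 429 and 1300 CPM (1.60), while Cxcl9 was lower at 463 and 193 CPM (-1.26). MHC class I genes were higher in 15 of 23 members (median 0.78), as in H2-T22 (2.14) and H2-K1 (1.23). Cd274 (1.16), Cd40 (1.29), Cd86 (0.74) and Il15 (2.42) were higher, as was the death ligand gene Tnfsf10 (2.59), and the DC activation list had a median of 0.24, or 0.05 with TMM scaling, with 10 of its 26 members higher, 3 lower and 7 below 10% of another class. The inflammatory list had 9 of 23 members higher and 3 lower (median 0.30, with TMM scaling 0.12), with Nos2, the inducible nitric oxide synthase, at 1.11, Ly6c2 at 2.35, the Fc receptor Fcgr1 at 1.27 and Il1a at -1.16. The tissue-resident and suppressive list went both ways, with 8 of 25 members higher and 2 lower (median 0.22, with TMM scaling 0.03): Retnla stood at 2.28, the scavenger receptor Cd163 at 1.59, Folr2 at 1.07 and Chil3 at -1.22. Chemokine genes had a median of 0.49, with 9 of 21 higher and 4 lower, and the monocyte attractants Ccl7 stood at 1.94 and Ccl2 at 1.07.

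The glycolysis list was lower in 6 of 24 members and higher in 1 (median -0.28), with Gapdh at -1.16 and Eno1 at -0.79, and the early response and heat shock list had a median of -0.06, with the chaperonin gene Hspe1 at -0.82. The TIM3 and interferon receptor list had a median of 0.14 that turned to -0.04 with TMM scaling, with Havcr2 at 0.33 and Ifnar1 at 0.03. T cell lists were higher too (cytotoxicity median 1.62), but 20 of its 29 members lay below 10% of another class, and Gzmb, at 11.7 and 114 CPM, lay far below its level in CD8 T-like cells. Malat1 was higher (1.13). Cluster 4 held 22.4% of the class in Ctrl and 1.73% in BiDT, cluster 14, led by cell cycle genes, 8.38% and 0.39%, cluster 3 0.34% and 29.5%, and cluster 13, led by interferon genes, 0.52% and 11.4%. Cluster 13 formed although the genes of the interferon lists had been left out of the clustering. Of the lowest ratios, Mgl2, Fn1 and Aldoc were among the leading genes of cluster 4, and Mki67, Pclaf and Birc5 among those of cluster 14. Their ratios may reflect the smaller BiDT shares of these clusters, lower expression within cells, or both, which was not tested.

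**Figure D2:**
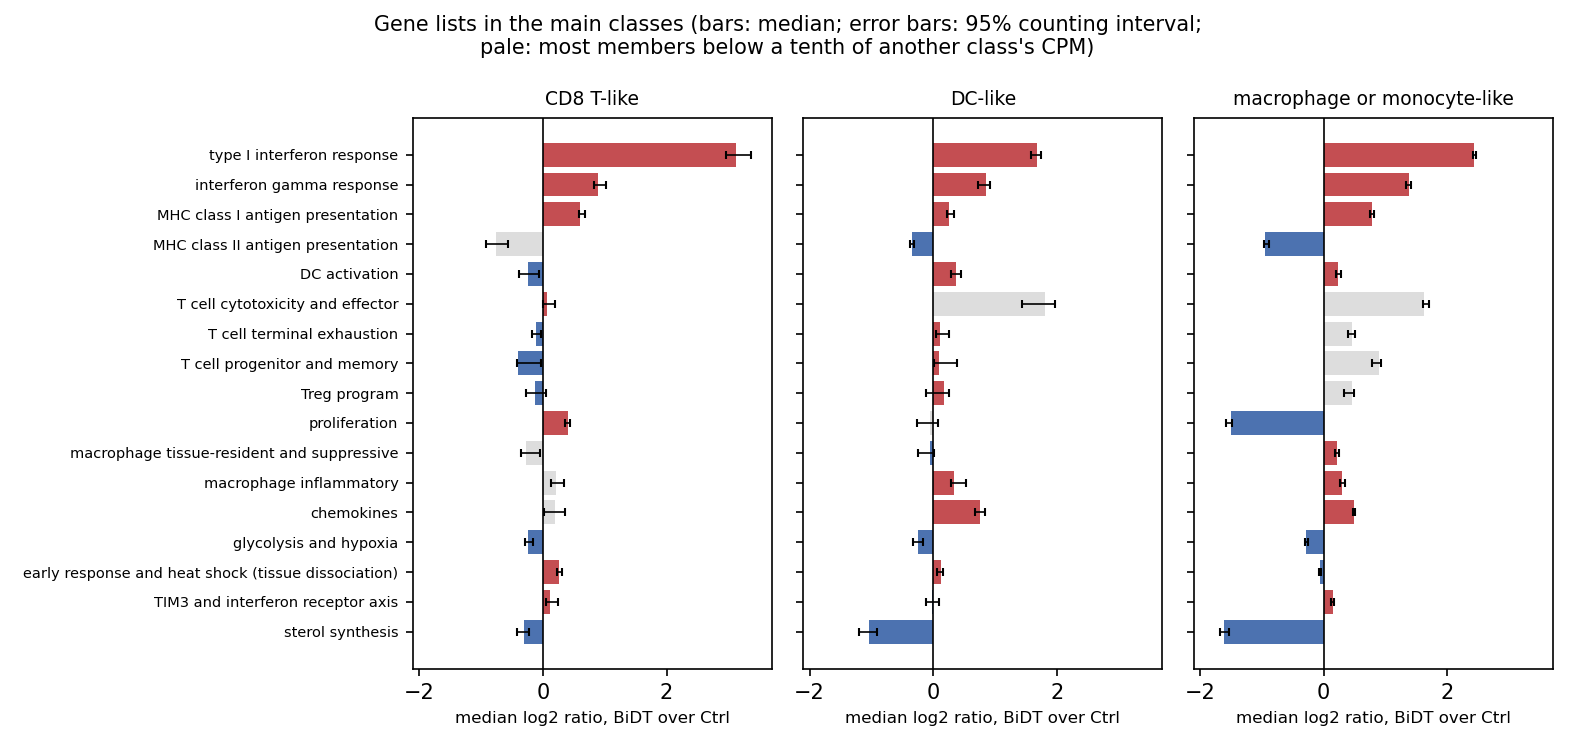
Median log2 ratio of BiDT over Ctrl (horizontal axis) for each gene list in CD8 T-like, DC-like and macrophage or monocyte-like cells, as bars with 95% counting intervals, in red above 0, in blue below 0 and in pale grey where most members lay below 10% of another class's CPM. The type I interferon list stood at 3.13, 1.68 and 2.44, and the proliferation list at 0.41, -0.05 and -1.51.

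Over all filtered cells, where differing cell classes add to differences within them, interferon genes again held the top. Of the 10 highest ratios, 7 were type I interferon list genes, including Ifit3b (4.94), Ifit1bl1 (4.53), Ifi44 (4.53), Ifit3 (4.24), Ifi208 (3.90), Ifit1 (3.79) and Ifit2 (3.59), and the others were Ifi214 (4.60), Slfn4 (4.32) and Ddx60 (3.58). All 46 list members were at least 1.5 times higher (median 2.22). Cytotoxicity genes had a median of 1.53, with Gzmb at 132 and 1196 CPM (3.18) and Ifng at 25.9 and 124 CPM (2.25), alongside the higher shares of NK-like and CD8 T-like cells. The lowest ratios were Fn1 (-2.52), Mgl2 (-2.40), the chemokine Ccl17 (-2.30), Aldoc (-2.23), Fdps (-2.17), Plet1 (-2.08), Acp5 (-1.95), Scd2 (-1.89), Cd81 (-1.87) and H2-Eb1 (-1.85), several of them genes of macrophages or dendritic cells, and the MHC class II list had a median of -1.39. Mki67 was level at 187 and 188 CPM.

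The type I interferon list was higher in BiDT in every class with at least 50 cells in each library. Beside the classes above, its median log2 ratio was 3.09 in fibroblast-like cells (3.04 to 3.23), 2.78 in regulatory T-like cells, 2.51 in NK-like cells, 2.35 in gamma delta T-like cells (1.31 in thinned counts), 1.78 in migratory DC-like cells, 1.64 in cDC2-like cells, 1.36 in neutrophil-like cells and 1.24 in cDC1-like cells (0.88 to 1.39). In each of these classes the median lay at percentile 100 of 10000 random lists matched on expression.

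**Figure D3:**
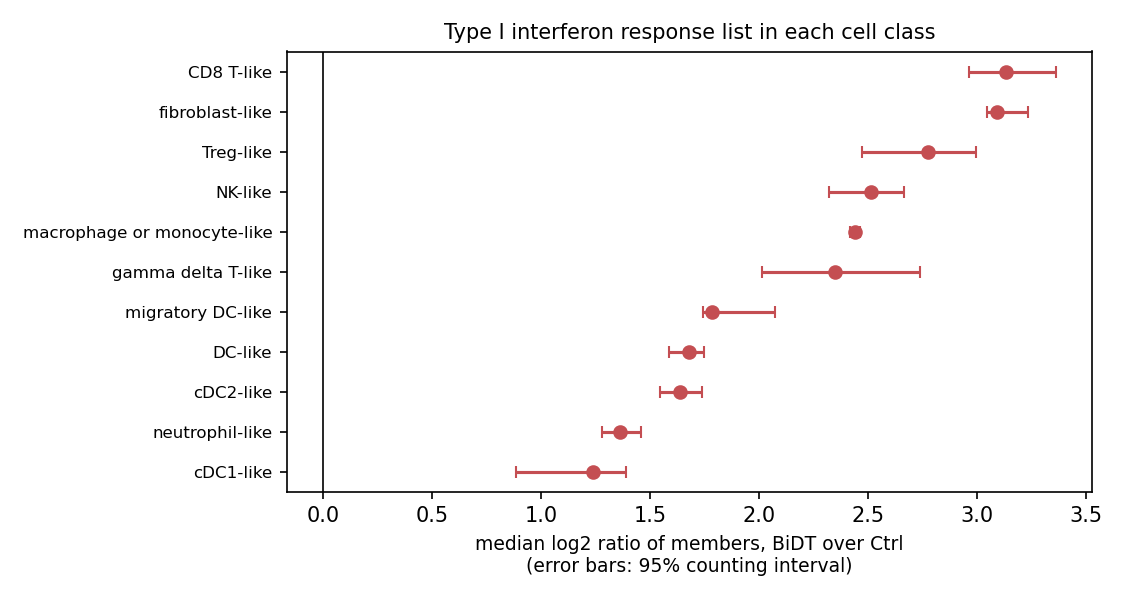
Median log2 ratio of BiDT over Ctrl of the type I interferon list (horizontal axis) in each class, as points with 95% counting intervals. All 11 classes, DC-like cells and their subsets included, lie above 0, from 1.24 in cDC1-like to 3.13 in CD8 T-like cells.

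Havcr2, the gene of TIM3, was detected in CD8 T-like cells, dendritic subsets, regulatory T-like cells and macrophages, most often in CD8 T-like cells at equal depth. After thinning each cell to 1000 UMIs, 18.4% of Ctrl (16.7 to 20.2%) and 23.8% of BiDT (22.4 to 25.2%) CD8 T-like cells had a Havcr2 UMI, at 239 and 317 CPM. Conventional DC-like cells carried it as well, in 13.0% of Ctrl and 16.4% of BiDT cDC2-like cells (146 and 156 CPM) and 14.0% and 19.2% of cDC1-like cells (178 and 175 CPM). In regulatory T-like cells the shares were 12.5% and 14.4% (123 and 165 CPM), in macrophage or monocyte-like cells 11.3% and 12.5% (112 and 141 CPM), in migratory DC-like cells 6.62% and 5.23%, in neutrophil-like cells 7.64% and 4.60%, in NK-like cells 3.45% and 3.37% and in gamma delta T-like cells 3.03% and 3.19%. As background, fibroblast-like cells, taken as a class without the gene although fibroblasts and tumour cells were not told apart in it, gave 0.67% and 1.21% at 8.70 and 14.3 CPM, with median depths of 9691 and 4424 UMIs against 3130 and 2617 UMIs in CD8 T-like cells. No B-like cell gave a UMI after thinning, of 7 in Ctrl and 21 in BiDT, where exact intervals allow up to 41.0% and 16.1%. Without thinning the shares were 44.4% and 49.7% in CD8 T-like, 46.7% and 38.5% in cDC1-like, 40.7% and 31.6% in cDC2-like, 28.4% and 24.8% in regulatory T-like, 38.4% and 30.0% in macrophage or monocyte-like, 35.4% and 26.1% in all DC-like and 8.12% and 8.19% in fibroblast-like cells. Without thinning cDC1-like cells thus stood above CD8 T-like cells in Ctrl, and the BiDT share, above that of Ctrl after thinning, lay below it in cDC1-like, cDC2-like, all DC-like, regulatory T-like, gamma delta T-like (9.09% and 5.32%) and macrophage or monocyte-like cells, the last at 4355 and 2601 UMIs per cell. For cDC1-like, migratory DC-like, NK-like and gamma delta T-like cells the shares give no order, since the CPM went the other way.

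**Figure D4:**
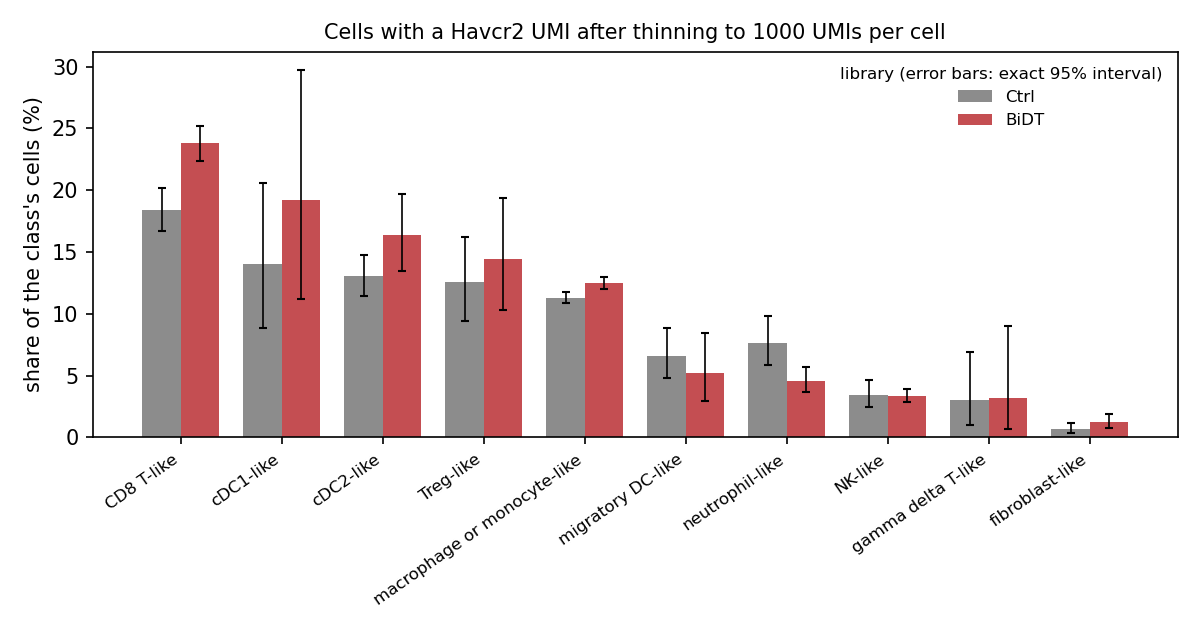
Share of cells with a Havcr2 UMI (%, vertical axis) per class with at least 50 cells in each library, after thinning each cell to 1000 UMIs, for the Ctrl (grey) and BiDT (red) libraries, with exact 95% binomial intervals as error bars. CD8 T-like cells stood highest, at 18.4% and 23.8%, and fibroblast-like cells, the background, at 0.67% and 1.21%.

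CD8 T-like cells with a Havcr2 UMI had moderately higher medians of the effector and exhaustion lists than cells without one, with few members past 1.5 times, and the interferon genes were higher in BiDT in both kinds of cells. In thinned counts, 365 Ctrl and 841 BiDT cells had a UMI, and 1619 and 2696 had none. Cytotoxicity genes were higher in cells with a UMI by a median log2 ratio of 0.35 in Ctrl and 0.30 in BiDT, and exhaustion genes, with Havcr2 itself left out, by 0.31 and 0.25. At least 1.5 times higher were 7 of 26 cytotoxicity members in Ctrl and 6 of 26 in BiDT, with none lower, and 2 of 17 exhaustion members in Ctrl, with 1 lower, and 1 of 17 in BiDT, with none lower. Gzmb stood at 0.58 and 0.50, Ifng at 0.48 and 0.66, the receptor gene Lag3 at 0.53 and 0.50 and the pore-forming Prf1 at 0.70 and 0.62. In BiDT the ratios of Pdcd1 (0.04), Tox (0.13), Ctla4 (0.07), Tigit (-0.001) and Entpd1 (0.25) had intervals that include 0, while in Ctrl those of Pdcd1 (0.25), Ctla4 (0.32), Tigit (0.59) and Entpd1 (0.92) lay above 0 and that of Tox (-0.12) included it. The libraries were not tested against each other in this. The proliferation list had medians of -0.33 and -0.32, with 8 of 25 members at least 1.5 times lower and 1 higher in Ctrl and 3 of 26 lower and none higher in BiDT. Of the type I interferon list, 20 members were measured in Ctrl and 44 in BiDT. This list barely differed, at 0.00 (-0.19 to 0.17) in Ctrl and 0.08 (0.02 to 0.13) in BiDT. Between the libraries its median was 2.94 (2.74 to 3.44) in cells with a UMI, where all 39 measured members were at least 1.5 times higher, and 3.02 (2.81 to 3.27) in cells without one, where all 44 were. A cell without a UMI can still express the gene, which blurs the split.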

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

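The sterol synthesis list and the setting that leaves out cells with over 1% Malat1 were chosen only after the data had been seen, while the tests run on them, like the other tests here, were fixed before their own results.

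Fibroblast-like cells, a class that a sort on CD45 should remove, made up 5.38% of filtered cells in Ctrl and 5.20% in BiDT. The ratio of these shares depended on the processing, as given below. Clusters that could not be named held 2.61% of Ctrl and 5.005% of BiDT cells.

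The type I interferon list was higher in the BiDT library in CD8 T-like cells, with a median log2 ratio of 3.13. Free RNA from macrophage or monocyte-like cells was argued against, since the list members stood at a median of 11.8 times the level that free RNA could give, with 46 of 46 members above that level. After thinning each cell to the same number of UMIs the median was 3.15. Thinning leaves the expected share of a gene within a cell unchanged and only gives cells equal weight. This value therefore does not decide whether the difference in depth played a part. A treatment effect and another difference between the pools of animals cannot be told apart with 1 library per group. An interferon response to the treatment thus may account for the pattern, as a hypothesis that these libraries cannot decide.

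The proliferation list was lower in the BiDT library in macrophage or monocyte-like cells, with a median of -1.51, and a cluster led by cell cycle genes held 8.38% of the class in Ctrl and 0.39% in BiDT. After thinning, which gives cells equal weight and leaves a gene's expected share within a cell unchanged, the median was -1.18. That cluster had a median of 8509 UMIs per cell, against 4355 in Ctrl cells of the class, so its cells weigh more in summed counts. The thinned value therefore does not decide on depth. In cells with Malat1 at 1% or less the list median was -1.57, which argues against nuclear-rich cells as the cause. Doublets with cycling non-immune cells were argued against by fibroblast markers, which in Ctrl cells with a Mki67 UMI stood at a median of 0.013 of their level in fibroblast-like cells, and at 0.014 in cells without one. Cells with a UMI of any proliferation gene after thinning made up 51.0% in Ctrl and 50.3% in BiDT. These shares lie far above the 8.38% of the cell cycle cluster in Ctrl. The measure is thus too coarse to show whether cycling cells were fewer. A treatment effect stays open as untested.

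Sterol synthesis genes were lower in the BiDT library in macrophage or monocyte-like cells, with a median of -1.61. In cells with Malat1 at 1% or less the median was -1.55, which argues against nuclear-rich cells as the whole cause. In cells with no UMI of a proliferation gene it was -1.26 in thinned counts, beside -1.31 in all cells of the class thinned alike, which argues against fewer cycling macrophages. A treatment effect on sterol synthesis may account for the pattern and stays open as a hypothesis, beside any other difference between the pools. Whether the different clusters that fill the class in each library set part of it was not tested.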

How the results depend on the processing

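The doublet thresholds of 0.1 and 0.2, the cells above the lowest Ctrl total, the Malat1 setting and the setting without the CD8 criterion were chosen after seeing the data. No paired analysis was possible because each group is 1 library and no test was run. Of the values that answer a comparison, 120 stayed within the counting interval of the reported value, 18 left it and 1 changed sign, and of all others 3631 stayed, 1036 left it and 16 changed sign. All values here are log2 ratios, and the cause of each shift was not tested. The type I interferon median ranged from 2.99 to 3.30 in CD8 T-like cells over 16 alternatives, the NK-like share from 2.05 to 2.14 over 11 and the CD8 T-like share from 0.73 to 0.82 over 12. The fibroblast-like share ranged from -1.38 to 0.06 over 11 (reported -0.05). Depth limits genes of few UMIs in either library, such as Tcf7 in CD8 T-like cells, where 44 and 54 UMIs gave a ratio of -0.40 with an interval of -0.999 to 0.21.

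With at most 5% mitochondrial UMIs the macrophage or monocyte-like share was -0.34 and the interferon median of that class 2.42 (reported -0.39 and 2.44). At a Leiden resolution of 2 that share was -0.43 and that median 2.48, the cDC1-like share of DC-like cells turned to -0.028 (reported 0.44), and the migratory share was 0.47 (reported 0.20). With Malat1 at 1% or less the macrophage or monocyte-like share was -0.44, the DC-like share -1.72 (reported -1.44), the DC-like interferon median 1.55 (reported 1.68) and Cd86 over all cells -0.15. The macrophage or monocyte-like interferon median was 2.47 with doublets kept, 2.18 thinned, 2.25 with TMM, 2.36 with median-of-ratios factors and 2.16 as a mean over cells. The DC-like interferon median was 1.52 with the interferon lists kept in the clustering and 1.53 with TMM. TMM also turned the DC-like exhaustion (-0.041), progenitor (-0.053) and early response (-0.029) medians, the last also as a mean over cells (-0.004), the macrophage or monocyte-like TIM3 list (-0.042) and Ifnar2 (-0.065), and over all cells the proliferation (-0.17), inflammatory (-0.092) and TIM3 (-0.026) lists. Median-of-ratios factors turned the all-cell proliferation (-0.11) and inflammatory (-0.032) lists, and thinning the all-cell inflammatory (-0.044) and the CD8 T-like TIM3 (-0.021) lists. Without a UMI minimum the CD8 T-like chemokine median was -0.067. Without thinning the log2 ratio of the Havcr2 share was 0.16 in CD8 T-like cells (reported 0.37) and -0.36 in macrophage or monocyte-like cells. With at least 2 Havcr2 UMIs the interferon ratio of CD8 T-like cells with to without was -0.23 in Ctrl and 0.15 in BiDT.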

Other observations

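The test of the hypothesis on Havcr2 was fixed after interferon medians of other classes had been seen but before that of fibroblast-like cells, and the genes named here were chosen after the data had been seen.

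NK-like cells of the BiDT library carried more effector transcripts of some kinds, with Gzmb at 1277 CPM in Ctrl and 3093 CPM in BiDT (log2 1.28) and Ifng at 72.1 and 140 CPM (0.96), while the cytotoxicity list went both ways, with 7 of 28 members at least 1.5 times higher and 8 lower (median -0.16, between -0.29 and -0.06 over 15 alternatives). Their interferon gamma list was higher in 15 of 24 members and lower in 3 (median 0.65), and proliferation genes had a median of 0.33, with Mki67 at 0.32. Cluster L2 held 50.5% of these cells in Ctrl and 18.1% in BiDT. In regulatory T-like cells 14 of 24 proliferation genes were at least 1.5 times lower and 1 higher (median -0.79, but -0.11 in thinned counts), with Mki67 at 406 and 203 CPM (-1.002), while Foxp3 stood at 586 and 503 CPM (-0.22) and the regulatory T cell program at a median of 0.15 (-0.04 to 0.27). Neutrophil-like cells had Cxcl10 at 869 and 1470 CPM (0.76) and Cd274 at 1407 and 1526 CPM (0.12).

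In fibroblast-like cells 20 of 25 members of the interferon gamma list were at least 1.5 times higher (median 1.61), as were 14 of 23 MHC class I genes (median 0.90). Which interferon raised the members of the interferon gamma list was not tested in any class. Cytotoxicity genes, which belong to other cell types, were higher in 23 of 26 members (median 1.96), early response and heat shock genes in 12 of 22 (median 0.60), and Malat1 by 1.62, the largest Malat1 ratio among the classes measured. In these cells Cxcl10 stood at 197 and 1559 CPM (2.99) and Cd274 at 22.7 and 64.6 CPM (1.51). They expressed Sparc at 1310 and 759 CPM and the chondrogenic factor Sox9 at 454 and 503 CPM, with Krt8 at 0.2 and 0.8 CPM and Epcam at 0.2 and 0.5 CPM, and these markers do not tell fibroblasts from cells of the MC38 line. Ptprc, the gene of CD45, stood at 34.5 and 65.7 CPM against 544 and 663 CPM in macrophage or monocyte-like cells. Among DC subsets, the DC activation list had a median of 0.42 in cDC2-like and 0.20 in migratory DC-like cells and -0.97 in cDC1-like cells, where 8 of 13 members were lower, in 150 Ctrl and 78 BiDT cells. Over 15 alternatives these medians ranged from 0.11 to 0.55, from 0.03 to 0.42 and from -1.24 to -0.08, the last value coming without a UMI minimum for genes.

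A hypothesis was that the interferon response appears only in classes with Havcr2 above background. Fibroblast-like cells, whose Havcr2 share served as background and which could hold tumour cells, had a type I interferon median of 3.09 (3.04 to 3.23), and in BiDT their members stood at a median of 9.59 times the free RNA level, with 44 of 45 above it. These values argue against a response restricted to such classes. They say nothing of which cells bound the protein, since an interferon or its inducers could also act on neighbouring cells, which was not tested.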
